A study of Rattus norvegicus with 16 samples.

How the data were processed

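The series measured gene expression in the plantaris muscle of Sprague Dawley rats described in the labels as retired breeders. In both hindlimbs the Achilles tendon was removed, which takes the gastrocnemius and soleus muscles out of action and puts the load on the plantaris, a procedure known as synergist ablation. Muscles were taken at day 0 (labelled as control muscle without overload) and at days 3, 7 and 28 after surgery, with 4 arrays per group and 16 arrays in all. The labels number the replicates but do not say that they came from separate animals, so p-values measure only the spread between these samples, which may be technical. Total RNA was labelled from 400 ng per reaction and hybridised to Affymetrix Rat Gene 2.1 ST arrays, per the labels.

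The deposited values are log2 expression values, 1 per transcript cluster and array, made with RMA, oligo and limma per the submitters' processing notes. Versions, order and parameters of those steps were not given in the sources used here, and no genome build or annotation release was named. The table held 36685 transcript clusters, with values from 0.0686 to 13.6. These ranges match a log2 RMA scale, on which very dim and very bright clusters are compressed. No depth in reads exists for arrays, and the number of arrays limits the precision. Scan dates and array batches were not used here, and no batch is named in the labels.

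Clusters were named through the platform annotation table that accompanied the values, which listed 15653 of them. Of these, 14824 had 1 gene symbol and 829 had several, and the other 21032 clusters of the table had no listed symbol and are unnamed here. For the 234 genes with more than 1 cluster, the cluster with the highest mean over all 16 arrays was used, which left 14557 genes for testing. A RefSeq gene table of the rat assembly GRCr8 held the gene identifiers of 14417 of the symbols and changed 0 of them. No coordinates were used. Of 18 genes fixed as a panel, 11 had a cluster of their own; Tnc, Myh1, Myh2, Myh8, Igf1, Pax7 and Mki67 did not and were not analysed here as genes.

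Differences between groups were tested with limma 3.58.1 in R 4.3.3. A group-means model over all 16 arrays was fitted to the deposited log2 values without further normalization, followed by empirical Bayes moderation without an intensity trend. Residual degrees of freedom were 12 and prior degrees of freedom 4.99. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called changed at an adjusted p under 0.05. The 5 comparisons were each later day against day 0, day 7 against day 3 and day 28 against day 7. In 14557 genes simulated for day 3 against day 0, 50 changed per size. The fit recovered 22% at log2 0.5, 72% at 1, 90% at 1.5 and 98% at 2. More were called at day 3, so recovery may rise.

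A set of 34 gene lists covered the extracellular matrix, contractile genes of fast, slow and developing fibres, myogenic regulators, energy metabolism, protein turnover, signalling, and markers of the cell types a muscle sample can hold. Of these, 33 had at least 2 measured members and were tested against all other genes with limma's camera at a preset correlation between genes of 0.01. The tests were adjusted over the lists within a comparison and repeated with the correlation estimated for each list. The list of sex-linked genes had 1 measured member of 7, which passed the threshold in 0 comparisons, so it was not tested and says nothing about the sex of the animals. Members past the threshold were counted over all genes tested and adjusted over the list alone.

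Genes are named by a fixed rule. It takes the 6 largest rises and the 6 largest falls of each comparison against day 0, and the 4 largest of each for successive days, among called genes whose 4 arrays all lie beyond the 4 arrays of the other group. From each list and comparison it takes up to 4 called members with the largest differences, and it takes the panel in every comparison. Symbols of predicted genes were passed over. Genes named outside this rule are said to have been chosen after their values were seen. The groups, the tests, the lists, the rule and the alternatives were fixed before the data were examined, except where a choice is stated to be later.

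Comparisons that share the day 0 arrays were set beside 100 draws of unchanged groups, made by dealing residuals of the fit to groups of 4, and beside the overlap that independent lists would give. They were also recomputed with the 4 day 0 arrays split 2 and 2 in the 6 possible ways. The alternatives tried were an intensity trend with robust priors, array weights, leaving out the dimmest 25% or 50% of genes, centring each array on its median over the tested genes, cyclic loess between arrays, the mean of a gene's clusters, and fitting only the compared groups. The replicate number as a fixed or random block, each array left out in turn, and all transcript clusters were tried as well. Centring on the median of the brighter 50% of genes was added after the array medians had been seen. List tests were not run with the random block, and neither they nor named genes were rerun over all clusters.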

Results

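Gene expression was measured on 16 arrays of rat plantaris muscle. Of these, 4 held control muscle without overload (day 0), and 4 each held muscle loaded for 3, 7 and 28 days after ablation of its synergists in both hindlimbs. The design follows load over time with no sham surgery, so load and surgery are not separated. The values were log2 expression values per transcript cluster, and the median over the 36685 clusters of an array lay between 3.19 and 3.41. Over the 14557 genes tested, array medians were 4.16 to 4.24 at day 0, 4.65 to 4.71 at day 3, 4.54 to 4.59 at day 7 and 4.42 to 4.49 at day 28. Differences are log2 differences between group means ± SE from limma, with n = 4 arrays per group, and a gene is said to have risen or fallen where its adjusted p was under 0.05. For a gene list, the members that rose and fell are counted over all genes tested, with the median log2 difference of the list. Counts adjusted over the list alone stand in parentheses where they differ and were otherwise the same. Values of dim clusters are compressed, so the difference of a gene whose mean in its lower group lay under the median of all clusters is a lower bound.

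The time points separated along the first principal component, which held 55.7% of the variance, with 9.2% on the second. Day 0 arrays lay between -53.8 and -50.0 on it, day 28 arrays between -29.4 and -18.1, day 7 arrays between 11.8 and 25.7 and day 3 arrays between 45.0 and 65.8. Pearson correlations across genes, which are not independent replicates, were 0.985 to 0.99 between arrays of the same day.

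**Figure D1:**
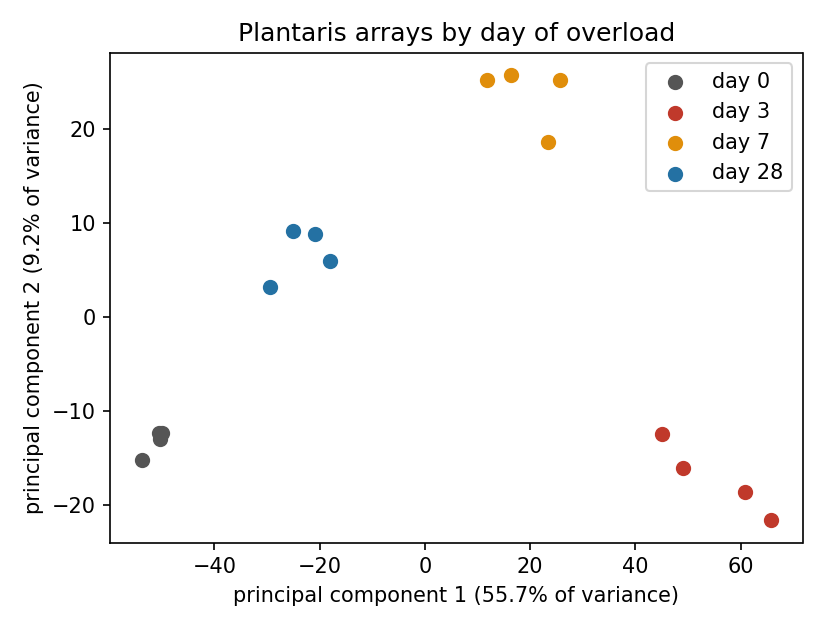
First and second principal components (score, with the share of variance on each axis) of the 14557 tested genes, with 1 point per array and 4 arrays per day, coloured by day. Day 0 arrays lie between -53.8 and -50.0 on the first component and day 3 arrays between 45.0 and 65.8, with the day 7 and day 28 arrays between them.

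At day 3 the largest measured rises over control muscle included those of Clec4a3, Lilrb4, Gpnmb and Ccr2, genes of myeloid immune cells. Clec4a3, a C-type lectin receptor of myeloid cells, rose by 6.07 ± 0.24 with adjusted p = 1.49e-11. Its day 0 mean of 3.34 lay under the median of all clusters on each day 0 array (3.36 to 3.41), as did those of Lilrb4 (3.04), Ccr2 (2.84) and Ly49si1 (1.57), so their differences are lower bounds and their order is open. Lilrb4, an inhibitory receptor of myeloid cells, rose by 5.93 ± 0.22, Gpnmb, a glycoprotein of macrophages, by 5.78 ± 0.18, and Ccr2, the chemokine receptor that draws monocytes out of the blood, by 5.58 ± 0.24. Ly49si1, of the Ly49 family of lectin-like receptors, rose by 5.85 ± 0.30, and Mt2A, a metal-binding metallothionein, by 5.55 ± 0.43. The largest falls were in Tecrl (-3.48 ± 0.33 with adjusted p = 1.42e-07) and Perm1, a muscle regulator of oxidative metabolism genes (-3.28 ± 0.33 with adjusted p = 3.61e-07). They were followed by Mir206, annotated as the gene of a muscle microRNA (-2.98 ± 0.69), Tigd4 (-2.94 ± 0.41), Tmem196 (-2.90 ± 0.23) and Pde7b, a cAMP phosphodiesterase (-2.87 ± 0.24). In each of these 12 genes the 4 day 3 arrays all lay beyond the 4 day 0 arrays.

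Macrophage genes and cytokines rose as groups. Of the macrophage and monocyte genes 20 of 20 rose and 0 fell (median 4.06, adjusted p = 1.05e-22). Fcgr1a, a high-affinity antibody receptor (5.11 ± 0.21), Msr1, a scavenger receptor (4.89 ± 0.29), and Cd68, a lysosomal protein of macrophages (4.78 ± 0.19), were among them. Of the cytokines and chemokines 18 of 23 rose and 0 fell (median 1.49, adjusted p = 8.38e-09). They included Ccl2, which attracts monocytes (4.99 ± 0.30), Il18 (4.21 ± 0.22) and Il1rn, the interleukin 1 receptor antagonist (3.48 ± 0.33). Of the lymphocyte and natural killer genes 7 of 17 rose and 0 fell (median 0.47, adjusted p = 0.0148, adjusted p = 0.219 with an estimated correlation). Cd8a (4.39 ± 0.22) and Cd8b (2.85 ± 0.26), chains of a co-receptor that rat macrophages can also carry, rose with Cd4 (3.01 ± 0.21). Of the neutrophil genes 1 of 11 rose and 1 fell (median 0.04, adjusted p = 0.929), and their median turned negative when arrays were centred on all tested genes (-0.42) or the brighter 50% (-0.11). Of the red blood cell genes 2 of 4 rose and 0 fell (3 and 0 adjusted over the list alone, median 1.38, adjusted p = 0.0593), namely Hba-a1 of haemoglobin (1.48 ± 0.20) and the haemoglobin chaperone Ahsp (1.45 ± 0.32). The red blood cell list passed under both centrings of the arrays, and without day 3 replicate 2 (median 1.48) or replicate 4 (1.61). Hbb-b1, a haemoglobin gene outside the list that was chosen after its values were seen, rose by 2.83 ± 0.27 at day 3, 1.84 ± 0.27 at day 7 and 2.14 ± 0.27 at day 28 against day 0.

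Matrix genes rose beside these. Of the fibrillar collagens and matrix glycoproteins 18 of 21 rose and 0 fell (median 2.63, adjusted p = 1.05e-15). Col1a1 rose by 4.35 ± 0.22 with adjusted p = 1.17e-10, Col3a1 by 3.79 ± 0.15 and Cthrc1, a secreted protein with collagen-like repeats, by 4.42 ± 0.28. Of the proteoglycan and hyaluronan genes 11 of 15 rose and 2 fell (median 1.25, adjusted p = 3.40e-05). Lum (3.66 ± 0.22), Aspn (3.27 ± 0.17) and Bgn (2.98 ± 0.18), small proteoglycans that bind collagen, were among them. Of the matrix proteases, inhibitors and crosslinkers 15 of 25 rose and 2 fell (median 1.81, adjusted p = 5.89e-07), led by the metalloprotease inhibitor Timp1 (5.48 ± 0.32) and the collagen crosslinker Lox (4.49 ± 0.18). Of the fibroblast and fibro-adipogenic progenitor markers 10 of 13 rose and 0 fell (median 1.72, adjusted p = 2.48e-06). They included S100a4 (4.51 ± 0.21), Pdgfra (2.33 ± 0.13) and Fap (2.16 ± 0.12). Of the basement membrane genes 5 of 8 rose and 2 fell (median 0.61, adjusted p = 0.117). Of the tenocyte genes 5 of 12 rose and 0 fell (median 0.40, adjusted p = 0.048, adjusted p = 0.415 with an estimated correlation), including Thbs4 (3.14 ± 0.21). That call was lost without the dimmest 25% or 50% of genes, under cyclic loess, with only the compared groups fitted, and without day 0 replicate 2 (median 0.24) or 3 (0.40), day 3 replicate 1 (0.34), day 7 replicate 2 or day 28 replicate 2 or 4 (0.40 each). The tenocyte median became -0.06 when arrays were centred on all tested genes.

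Genes of cell division also rose. Of the cell cycle genes 25 of 25 rose and 0 fell (median 2.63, adjusted p = 1.05e-15). Prc1, which bundles microtubules in dividing cells, rose by 3.59 ± 0.29, the cyclin Ccna2 by 3.54 ± 0.32 and Rrm2, a subunit of ribonucleotide reductase, by 3.42 ± 0.35. Of the ribosome biogenesis genes 12 of 23 rose and 3 fell (14 and 3 adjusted over the list alone, median 0.46, adjusted p = 0.00748, adjusted p = 0.322 with an estimated correlation), including Fbl, a nucleolar methyltransferase (1.03 ± 0.18). Of the proteasome genes 12 of 24 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.37, adjusted p = 0.00696, adjusted p = 0.537 with an estimated correlation), including Psma5 (1.17 ± 0.16). Both calls were lost without the dimmest 50% of genes and under centring on all tested genes, which turned the proteasome median to -0.09. Of the unfolded protein response and secretory chaperone genes 9 of 17 rose and 1 fell (median 0.55, adjusted p = 0.00696, adjusted p = 0.287 with an estimated correlation). Sdf2l1 (3.18 ± 0.33), Pdia6 (1.44 ± 0.13) and P4hb (1.42 ± 0.12), proteins of the endoplasmic reticulum, rose. Of the heat shock and load-responsive sarcomere genes 7 of 14 rose and 4 fell (8 and 4 adjusted over the list alone, median 0.60, adjusted p = 0.13), and Ankrd1, a stretch-responsive protein of the sarcomere, rose by 2.75 ± 0.18.

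Genes of energy metabolism fell in the same arrays. Of the tricarboxylic acid cycle and pyruvate dehydrogenase genes 0 of 14 rose and 14 fell (median -0.85, adjusted p = 5.57e-07, adjusted p = 0.255 with an estimated correlation). Idh3a (-1.38 ± 0.13 with adjusted p = 1.58e-07) and Dlat (-1.04 ± 0.14) were among them. Of the glycolysis and glycogen genes 0 of 12 rose and 12 fell (median -1.24, adjusted p = 8.58e-07, adjusted p = 0.219 with an estimated correlation). They included Fbp2, fructose bisphosphatase of muscle (-2.71 ± 0.33), Gys1, glycogen synthase (-1.50 ± 0.18), and Phkg1, of phosphorylase kinase (-1.92 ± 0.21). Of the fatty acid oxidation genes 0 of 24 rose and 18 fell (0 and 19 adjusted over the list alone, median -0.80, adjusted p = 4.48e-07, adjusted p = 0.287 with an estimated correlation), with Ppargc1a, a coactivator of mitochondrial genes (-2.37 ± 0.19), and Acsl1 (-1.68 ± 0.20). Of the oxidative phosphorylation genes 1 of 34 rose and 14 fell (median -0.30, adjusted p = 9.56e-04, adjusted p = 0.517 with an estimated correlation), with Sdha (-1.27 ± 0.16) and Atp5f1c (-1.34 ± 0.19). Of the calcium handling genes 1 of 11 rose and 7 fell (median -1.14, adjusted p = 0.00287, adjusted p = 0.193 with an estimated correlation). Jph2, which holds the membranes of the triad together (-2.37 ± 0.24), and Pln (-1.61 ± 0.30) fell, and Sln, an inhibitor of the calcium pump, rose (1.94 ± 0.25).

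Contractile genes moved both ways. Of the fast-fibre contractile genes 0 of 7 rose and 5 fell (median -0.77, adjusted p = 0.0211, adjusted p = 0.425 with an estimated correlation), a call lost without the dimmest 50% of genes. Myh4, the fast IIb myosin heavy chain, changed by -0.96 ± 0.21 with adjusted p = 0.0013 and Casq1 by -0.93 ± 0.14. Of the slow-fibre genes 4 of 11 rose and 6 fell (5 and 6 adjusted over the list alone, median -0.53, adjusted p = 0.783), with Myh7, the slow myosin heavy chain (-1.86 ± 0.26 with adjusted p = 1.41e-05), against Tpm3 (2.09 ± 0.18). Of the developmental contractile and receptor genes 2 of 6 rose and 0 fell (median 0.17, adjusted p = 0.336), and their median turned to -0.29 with centring on all tested genes. Tnnt2, the cardiac and embryonic troponin T, rose by 1.75 ± 0.33. Of the myogenic regulators and satellite cell genes 8 of 18 rose and 4 fell (median 0.12, adjusted p = 0.457), with a median that turned to -0.34 under that centring and to -0.03 with the brighter 50%. Myog, a regulator of muscle differentiation, rose by 2.27 ± 0.27, with Cd82 higher (2.59 ± 0.18) and Notch3 lower (-1.68 ± 0.19).

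Vessel genes were lower. Of the endothelial genes 1 of 13 rose and 8 fell (median -0.90, adjusted p = 0.00573, adjusted p = 0.322 with an estimated correlation). Flt1, a receptor for vascular endothelial growth factor, was among those that fell (-2.23 ± 0.25). Of the pericyte and smooth muscle genes 1 of 9 rose and 5 fell (1 and 6 adjusted over the list alone, median -0.99, adjusted p = 0.0179, adjusted p = 0.322 with an estimated correlation), including Lmod1 (-2.09 ± 0.23), a call lost under centring on all tested genes and without the dimmest 50%. Of the adipocyte genes 3 of 10 rose and 6 fell (3 and 7 adjusted over the list alone, median -0.62, adjusted p = 0.346), and of the Schwann cell and myelin genes 0 of 8 rose and 1 fell (median -0.11, adjusted p = 0.706). Median, mean and test differed in sign for 3 lists. Of the neuromuscular junction and denervation genes 2 of 11 rose and 4 fell (median -0.46, adjusted p = 0.691, mean 0.13, test downward). Of the TGF-beta, activin and BMP signalling genes 8 of 26 rose and 9 fell (median -0.06, adjusted p = 0.997, mean 0.09), and of the atrophy ligase and autophagy genes 6 of 16 rose and 4 fell (6 and 5 adjusted over the list alone, median -0.14, adjusted p = 0.929, mean 0.13). Of the insulin-like growth factor system 3 of 11 rose and 4 fell (median -0.10, adjusted p = 0.706), and cyclic loess turned this median to 0.01 and that of the TGF-beta list to 0.04.

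Of the panel genes, Mstn, the muscle growth inhibitor myostatin, changed by -1.55 ± 0.31 with adjusted p = 5.67e-04. Myh3, the embryonic myosin heavy chain (-0.44 ± 0.35, adjusted p = 0.342), Myod1 (-0.29 ± 0.23, adjusted p = 0.344) and the atrophy ligase Fbxo32 (-0.20 ± 0.20, adjusted p = 0.446) did not pass. With arrays centred on all tested genes these 3 passed, at -0.90, -0.75 and -0.67. Trim63, another atrophy ligase, rose by 0.76 ± 0.14 with adjusted p = 2.82e-04, with 1 day 3 array at 10.65 and the others at 10.37 to 10.41. Under centring on all tested genes its difference was 0.30 and did not pass.

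In limma, 6013 of 14557 genes (41.3%) had changed at day 3, 3156 higher and 2857 lower. At least 2-fold, 2472 had changed, 1650 higher and 822 lower. The arrays of the 2 days did not overlap in 5722 genes, where chance gives 2.86% of genes, and 6961 genes had an unadjusted p under 0.05. Of the 33 lists tested, 12 were called upward and 8 downward. With an estimated correlation 7 upward and 0 downward calls held, those of collagens, proteoglycans, matrix proteases, cell cycle, macrophages, cytokines and fibroblasts. Centring arrays on all tested genes shifted the differences from day 0 by -0.46, -0.36 and -0.25 at days 3, 7 and 28, from day 3 to 7 by 0.10 and from day 7 to 28 by 0.11. Centring on the brighter 50% shifted them by -0.16, -0.07, -0.06, 0.08 and 0.01, and cyclic loess by 0.10, 0.05, 0.01, -0.02 and -0.04. At day 3, 52.5% of changed genes were higher as deposited, 18.2% centred on all tested genes and 37.7% on the brighter 50%. The median gene differed by -0.052, -0.513 and -0.208 in turn. Centred on all tested genes, list medians were 3.60 (macrophages), 2.17 (collagens) and -1.31 (tricarboxylic acid cycle).

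**Figure D2:**
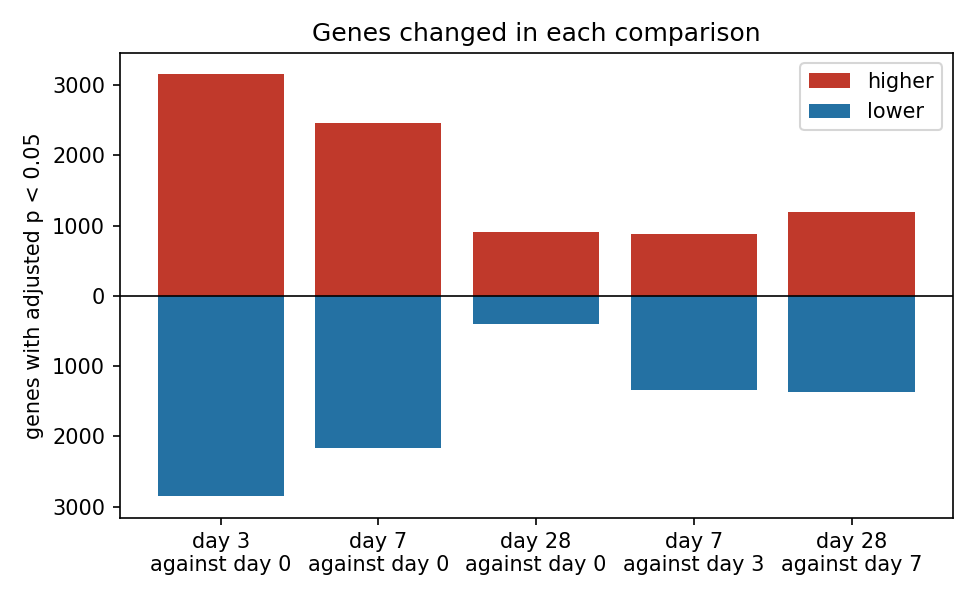
Number of genes (vertical axis) that were higher (bars above 0) or lower (bars below 0) with adjusted p under 0.05 in each of the 5 comparisons of groups of 4 arrays. Day 3 against day 0 has 3156 genes higher and 2857 lower, and day 28 against day 0 has 915 higher and 408 lower, a split that becomes 18.2% and 15.2% higher for these comparisons when arrays are centred on all tested genes.

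At day 7 matrix genes stood among the largest measured rises over control muscle. Cxcl13, a chemokine for B cells, rose by 5.79 ± 0.40 with adjusted p = 9.28e-09, Cthrc1 by 5.30 ± 0.28, Ccr2 by 4.73 ± 0.24, Col1a1 by 4.68 ± 0.22, Clrn1 by 4.42 ± 0.35 and Postn, the matrix protein periostin, by 4.36 ± 0.20. Below these, Mymk, which fuses myoblasts, rose by 3.42 ± 0.31 with adjusted p = 2.36e-07, and Myh3, the embryonic myosin heavy chain, by 2.60 ± 0.35 with adjusted p = 1.85e-05. The largest falls were in Perm1 (-2.95 ± 0.33 with adjusted p = 3.20e-06), Cish, an inhibitor of cytokine signalling (-2.77 ± 0.56), and Ubxn10 (-2.52 ± 0.25). Or52ab4, an olfactory receptor gene (-2.51 ± 0.36), Tigd4 (-2.39 ± 0.41) and B3galt1, a galactosyltransferase (-2.32 ± 0.30), followed.

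Matrix lists were again higher. Of the fibrillar collagens and matrix glycoproteins 20 of 21 rose and 0 fell (21 and 0 adjusted over the list alone, median 2.72, adjusted p = 4.95e-25), and Col3a1 rose by 3.71 ± 0.15. Of the basement membrane genes 5 of 8 rose and 0 fell (6 and 0 adjusted over the list alone, median 0.69, adjusted p = 0.00105, adjusted p = 0.0743 with an estimated correlation). Of the proteoglycan and hyaluronan genes 9 of 15 rose and 2 fell (11 and 2 adjusted over the list alone, median 1.33, adjusted p = 1.11e-05), with Aspn (3.98 ± 0.17) and Bgn (3.62 ± 0.18). Of the matrix proteases, inhibitors and crosslinkers 17 of 25 rose and 3 fell (median 1.71, adjusted p = 1.33e-09). Lox (3.64 ± 0.18), Loxl1 (3.49 ± 0.19) and Mmp14, a membrane-bound metalloprotease (3.31 ± 0.19), rose. Of the fibroblast markers 11 of 13 rose and 0 fell (median 1.92, adjusted p = 7.44e-10), with S100a4 (4.27 ± 0.21) and Fap (2.74 ± 0.12). Of the tenocyte genes 6 of 12 rose and 0 fell (9 and 0 adjusted over the list alone, median 1.05, adjusted p = 1.67e-04, adjusted p = 0.125 with an estimated correlation), with Cilp of cartilage and tendon matrix (2.94 ± 0.21) and the transcription factor Egr1 (1.92 ± 0.25).

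Of the developmental contractile and receptor genes 6 of 6 rose and 0 fell (median 1.79, adjusted p = 1.81e-05). Tnnt2 rose by 3.99 ± 0.33, Chrna1, a subunit of the acetylcholine receptor, by 2.04 ± 0.44, and Mybph by 1.54 ± 0.24. Of the myogenic regulators and satellite cell genes 8 of 18 rose and 1 fell (median 0.48, adjusted p = 0.00956, adjusted p = 0.0892 with an estimated correlation), a call lost without the dimmest 50% of genes. Myf5, a regulator of myoblasts (1.84 ± 0.20), Cd82 (1.91 ± 0.18) and Myog (1.36 ± 0.27 with adjusted p = 8.39e-04) rose, and Myod1 differed by 0.47 ± 0.23 (adjusted p = 0.125). Of the neuromuscular junction genes 4 of 11 rose and 0 fell (median 0.19, adjusted p = 0.0509), including Chrng, the fetal subunit of the acetylcholine receptor (1.53 ± 0.20). That list passed without day 0 replicate 1 (median 0.22) or 4 (0.10) or day 7 replicate 2 (0.23) or 3 (0.18), with an intensity trend and with the mean of a gene's clusters. It also passed upward under centring on the brighter 50% (adjusted p = 0.0446) and on all tested genes (adjusted p = 0.0334), where its median became -0.17. Of the fast-fibre genes 0 of 7 rose and 2 fell (median -0.24, adjusted p = 0.326). Myh4 differed by -0.52 ± 0.21 (adjusted p = 0.0717), and passed without day 3 replicate 2 (-0.52) or day 7 replicate 1 (-0.64), under centring on all tested genes (-0.88) or the brighter 50% (-0.60), with an intensity trend, without the dimmest 50% of genes and with only the compared groups fitted. Of the slow-fibre genes 4 of 11 rose and 2 fell (median 0.24, adjusted p = 0.327), with a median of -0.12 under centring on all tested genes. Of the calcium handling genes 1 of 11 rose and 4 fell (median -0.22, adjusted p = 0.327), and Sln rose by 3.02 ± 0.25.

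Myh7 (-0.85 ± 0.26 with adjusted p = 0.0188) and Mstn (-0.97 ± 0.31 with adjusted p = 0.0242) were lower, but both calls were lost without single arrays. Myh7 differed by -0.69 without day 7 replicate 4, -0.74 without day 0 replicate 4 and -0.79 without day 7 replicate 2. Mstn differed by -0.90 without day 0 replicate 4 or day 7 replicate 3 and -0.92 without day 7 replicate 2. The ligase Fbxo32 fell (-1.11 ± 0.20 with adjusted p = 3.14e-04), and Trim63 differed by 0.11 ± 0.14 (adjusted p = 0.601).

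Immune genes were still above control muscle. Of the macrophage genes 19 of 20 rose and 0 fell (median 2.68, adjusted p = 3.07e-22), with Gpnmb (4.08 ± 0.18), lysozyme Lyz2 (3.30 ± 0.19) and Cd68 (3.17 ± 0.19). Of the lymphocyte and natural killer genes 11 of 17 rose and 0 fell (12 and 0 adjusted over the list alone, median 0.90, adjusted p = 1.56e-04), including Cd4 (3.28 ± 0.21). Of the cytokines and chemokines 13 of 23 rose and 0 fell (15 and 0 adjusted over the list alone, median 0.95, adjusted p = 1.93e-07), with Ccl2 (3.44 ± 0.30) and Ccl24 (2.15 ± 0.25). Of the neutrophil genes 1 of 11 rose and 1 fell (0 and 1 adjusted over the list alone, median 0.03, adjusted p = 0.932, test downward), with Lcn2 lower (-1.09 ± 0.23). Of the red blood cell genes 1 of 4 rose and 0 fell (median 0.35, adjusted p = 0.422), with a median that became -0.01 under centring on all tested genes. Of the cell cycle genes 12 of 25 rose and 1 fell (13 and 1 adjusted over the list alone, median 0.60, adjusted p = 0.00187, adjusted p = 0.394 with an estimated correlation), a call lost without the dimmest 50% of genes.

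Energy metabolism genes were lower at day 7 too. Of the tricarboxylic acid cycle genes 0 of 14 rose and 10 fell (0 and 14 adjusted over the list alone, median -0.58, adjusted p = 1.45e-05, adjusted p = 0.302 with an estimated correlation), with Idh3a (-0.75 ± 0.13). Of the fatty acid oxidation genes 0 of 24 rose and 15 fell (0 and 16 adjusted over the list alone, median -0.58, adjusted p = 1.11e-05, adjusted p = 0.312 with an estimated correlation), with Ppargc1a (-1.39 ± 0.19) and Pdk4, which restrains pyruvate dehydrogenase (-1.33 ± 0.27). Of the glycolysis and glycogen genes 0 of 12 rose and 10 fell (0 and 11 adjusted over the list alone, median -0.79, adjusted p = 1.81e-05, adjusted p = 0.274 with an estimated correlation), with Fbp2 (-1.50 ± 0.33) and Pkm, pyruvate kinase (-0.98 ± 0.14). Of the oxidative phosphorylation genes 0 of 34 rose and 9 fell (median -0.21, adjusted p = 0.0128, adjusted p = 0.688 with an estimated correlation), with Sdha (-0.89 ± 0.16). Of the endothelial genes 0 of 13 rose and 6 fell (1 and 7 adjusted over the list alone, median -0.61, adjusted p = 0.00408, adjusted p = 0.312 with an estimated correlation), with Flt1 (-2.02 ± 0.25) and Cdh5, the cadherin of endothelial junctions (-1.39 ± 0.20). Of the pericyte and smooth muscle genes 1 of 9 rose and 4 fell (2 and 5 adjusted over the list alone, median -0.46, adjusted p = 0.254), with Lmod1 lower (-2.16 ± 0.23) and Pdgfrb higher (1.41 ± 0.18). Of the proteasome genes 12 of 24 rose and 1 fell (15 and 1 adjusted over the list alone, median 0.36, adjusted p = 0.00155, adjusted p = 0.572 with an estimated correlation), a call lost under centring on all tested genes, where the median was 0.01.

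The other lists were not called. Of the heat shock and load-responsive sarcomere genes 7 of 14 rose and 2 fell (median 0.29, adjusted p = 0.0572), with Ankrd1 (2.80 ± 0.18). This list passed without day 0 replicate 3 (median 0.33) or 4 (0.31) or day 7 replicate 3 (0.30) and with an intensity trend. Centring on all tested genes turned its median to -0.07 while the list passed upward (adjusted p = 0.042), and turned negative the medians of ribosome biogenesis (median 0.07, adjusted p = 0.901), the unfolded protein response (median 0.07, adjusted p = 0.311) and TGF-beta signalling (median 0.07, adjusted p = 0.631). Median and mean or test differed in sign for adipocytes (median -0.22, adjusted p = 0.957, mean 0.12) and Schwann cells (median 0.01, adjusted p = 0.924, mean -0.03). They also did for the insulin-like growth factor system (median -0.12, adjusted p = 0.902, mean 0.09), atrophy ligases (median 0.03, adjusted p = 0.927, test downward) and neutrophils. The medians for Schwann cells, atrophy ligases and neutrophils turned negative under that centring.

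At this day 4617 genes (31.7%) had changed in limma, 2455 higher and 2162 lower, and 1432 at least 2-fold, 1084 higher and 348 lower. Arrays did not overlap in 4667 genes (2.86% by chance). Of the lists, 13 were called upward and 5 downward, and 8 upward calls and 0 downward calls held with an estimated correlation. They were those of collagens, proteoglycans, matrix proteases, developmental genes, macrophages, lymphocytes, cytokines and fibroblasts. The share of changed genes that were higher was 53.2% as deposited and 16.8% after centring on all tested genes.

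**Figure D3:**
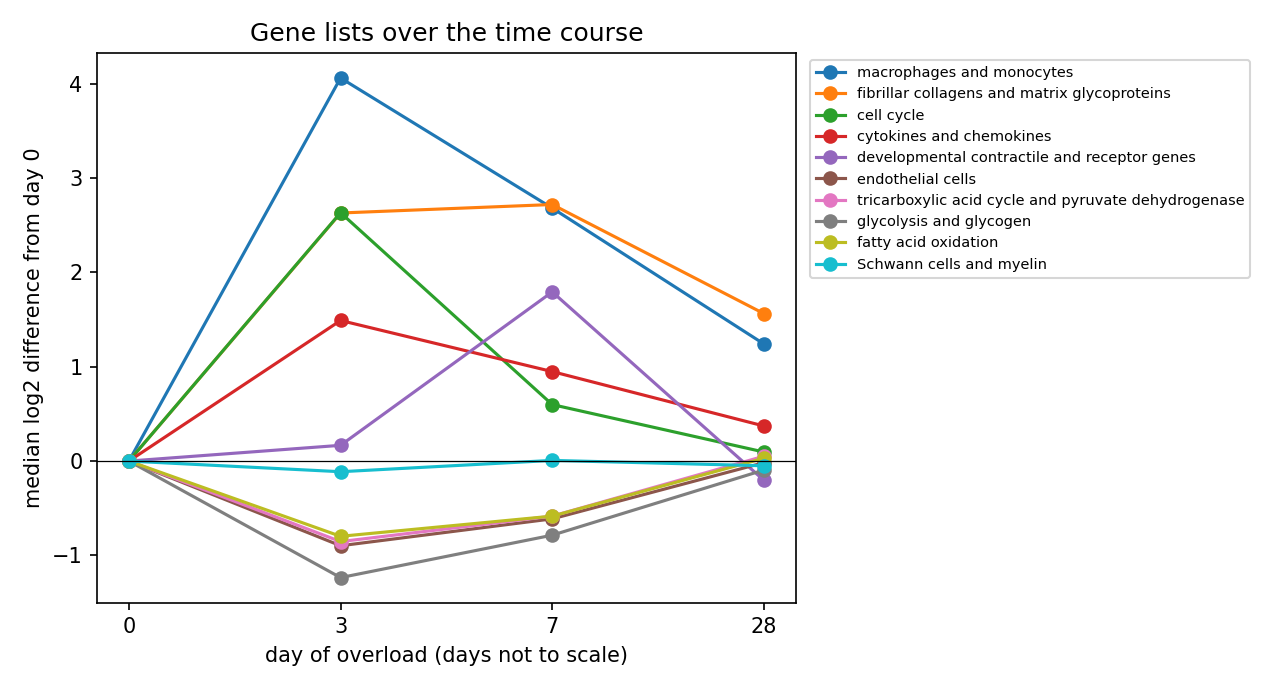
Median log2 difference from day 0 (vertical axis) of 10 gene lists at days 0, 3, 7 and 28 (horizontal axis, days not to scale), with 1 line per list and 4 arrays per day. The macrophage median is 4.06 at day 3 and 1.24 at day 28, the collagen median 2.72 at day 7 and the glycolysis median -1.24 at day 3, and the developmental median of 0.17 at day 3 turns to -0.29 when arrays are centred on all tested genes, as do the signs of the cell cycle, tricarboxylic acid cycle and fatty acid oxidation medians at day 28 and the Schwann cell median at day 7.

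After 28 days matrix and macrophage genes were above control muscle. Col1a1 was higher by 2.68 ± 0.22 with adjusted p = 1.12e-06, Ccr2 by 2.64 ± 0.24, Cxcl13 by 2.54 ± 0.40, Dynap by 2.70 ± 0.51, Pi15, a peptidase inhibitor, by 2.51 ± 0.38 and Clrn1 by 2.49 ± 0.35. Myh3 had fallen below control muscle (-2.61 ± 0.35 with adjusted p = 1.13e-04), and of the other striated muscle myosin heavy chain clusters with a mean above 5 the lowest difference was -0.23. The next largest falls were in Kcnj3, a potassium channel subunit (-1.77 ± 0.26), Slc35f1 (-1.72 ± 0.24), Celsr2, a receptor of the cadherin family (-1.61 ± 0.21), Amy1, an amylase (-1.56 ± 0.33), and Irs1, an insulin receptor substrate (-1.49 ± 0.22).

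Of the fibrillar collagens and matrix glycoproteins 17 of 21 rose and 0 fell (19 and 0 adjusted over the list alone, median 1.56, adjusted p = 1.01e-27), with Col3a1 (2.37 ± 0.15) and Thbs2, a matricellular protein (1.95 ± 0.23). Of the basement membrane genes 3 of 8 rose and 0 fell (4 and 0 adjusted over the list alone, median 0.40, adjusted p = 0.00273, adjusted p = 0.127 with an estimated correlation), with Nid2 (1.39 ± 0.16). Of the proteoglycan and hyaluronan genes 7 of 15 rose and 0 fell (median 0.64, adjusted p = 2.90e-05), with Aspn (2.18 ± 0.17) and Ogn (1.30 ± 0.14). Of the matrix proteases, inhibitors and crosslinkers 13 of 25 rose and 1 fell (15 and 2 adjusted over the list alone, median 0.78, adjusted p = 5.45e-08), with Loxl2 (2.01 ± 0.22), Mmp14 (1.90 ± 0.19) and Mmp2 (1.76 ± 0.13). Of the fibroblast markers 8 of 13 rose and 0 fell (9 and 0 adjusted over the list alone, median 1.29, adjusted p = 1.28e-11), with Dpt, dermatopontin (1.89 ± 0.12), Pi16 (1.88 ± 0.27) and Fap (1.73 ± 0.12). Of the tenocyte genes 3 of 12 rose and 0 fell (median 0.59, adjusted p = 0.00634, adjusted p = 0.373 with an estimated correlation), with Thbs4 (1.39 ± 0.21) and Cilp (1.30 ± 0.21). The tenocyte call was lost without the dimmest 50% of genes or without day 28 replicate 4 (median 0.52).

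Of the macrophage genes 17 of 20 rose and 0 fell (18 and 0 adjusted over the list alone, median 1.24, adjusted p = 1.05e-18), with Adgre1, a surface receptor of macrophages (2.06 ± 0.25), Lyz2 (1.75 ± 0.19) and Cd68 (0.95 ± 0.19 with adjusted p = 0.00437). Of the cytokines and chemokines 4 of 23 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.37, adjusted p = 0.0179, adjusted p = 0.27 with an estimated correlation), with Ccl24 (2.24 ± 0.25) and Ccl2 (1.62 ± 0.30), a call lost without the dimmest 25% of genes. Of the red blood cell genes 2 of 4 rose and 0 fell (median 0.79, adjusted p = 0.0179, adjusted p = 0.373 with an estimated correlation), with Ahsp (1.42 ± 0.32) and Hba-a1 (1.04 ± 0.20), a call lost without the dimmest 25% of genes or day 28 replicate 4 (median 0.80). Of the lymphocyte and natural killer genes 1 of 17 rose and 0 fell (median 0.17, adjusted p = 0.271), the rise being that of Cd4 (1.87 ± 0.21). Of the neutrophil genes 0 of 11 rose and 1 fell (median 0.08, adjusted p = 0.679, with signs that differed), the fall being that of Lcn2 (-1.05 ± 0.23).

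Contractile and metabolic genes were mostly not called. Of the slow-fibre genes 3 of 11 rose and 0 fell (median 0.36, adjusted p = 0.0243, adjusted p = 0.519 with an estimated correlation). That call was lost without the dimmest 25% or 50% of genes and without day 0 replicate 1 (median 0.23), day 28 replicate 3 (0.27) or day 28 replicate 4 (0.18). Of the oxidative phosphorylation genes 1 of 34 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.18, adjusted p = 8.10e-04, adjusted p = 0.623 with an estimated correlation), with a median of -0.07 and no call under centring on all tested genes. Of the calcium handling genes 0 of 11 rose and 0 fell (median -0.25, adjusted p = 0.0455, adjusted p = 0.373 with an estimated correlation). This call was lost with array weights, the replicate block or centring on all tested genes (-0.50), and without day 0 replicate 1 (-0.23), 3 (-0.24) or 4 (-0.28) or day 28 replicate 4 (-0.21). The fast-fibre (median -0.13, adjusted p = 0.495), developmental (median -0.20, adjusted p = 0.224) and glycolysis lists (median -0.10, adjusted p = 0.198) were not called. The tricarboxylic acid cycle (median 0.05, adjusted p = 0.861) and fatty acid oxidation lists (median 0.03, adjusted p = 0.635) were not called either. Nor were the myogenic (median 0.07, adjusted p = 0.495) and cell cycle lists (median 0.10, adjusted p = 0.329), and the medians of these 4 turned negative under centring on all tested genes. Panel genes that did not pass were Myh4 (-0.23 ± 0.21, adjusted p = 0.571), Myh7 (-0.05 ± 0.26, adjusted p = 0.941) and Myod1 (-0.22 ± 0.23, adjusted p = 0.626). Myog (0.18 ± 0.27, adjusted p = 0.755), Fbxo32 (-0.29 ± 0.20, adjusted p = 0.431) and Trim63 (0.27 ± 0.14, adjusted p = 0.267) did not pass either. Mstn differed by -0.74 ± 0.31 (adjusted p = 0.157) and passed under centring on all tested genes and without day 3 replicate 4 (-0.75).

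Of the heat shock and load-responsive sarcomere genes 1 of 14 rose and 4 fell (1 and 6 adjusted over the list alone, median -0.28, adjusted p = 0.00626, adjusted p = 0.373 with an estimated correlation). Ccn1 (-1.06 ± 0.24) and the sarcomere protein Flnc (-0.86 ± 0.17) were lower and Myof, a protein of membrane repair, was higher (0.80 ± 0.19). The remaining lists were not called, with adjusted p between 0.198 for pericytes and 0.861 for the unfolded protein response, whose median, mean and test differed in sign. The medians of the lymphocyte, neutrophil, adipocyte, atrophy, proteasome and unfolded protein response lists turned from positive to negative under centring on all tested genes.

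The changed genes at day 28 numbered 1323 (9.1%) in limma, 915 higher and 408 lower, and 365 changed at least 2-fold, 338 higher and 27 lower. Arrays did not overlap in 2312 genes (2.86% by chance). List calls were 11 upward and 2 downward. Of these, 5 upward (collagens, proteoglycans, matrix proteases, macrophages and fibroblasts) and 0 downward held with an estimated correlation. The share of changed genes that were higher was 69.2% as deposited, 15.2% after centring on all tested genes and 53.7% after centring on the brighter 50%.

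From day 3 to day 7 genes of cell division and of macrophages fell, and genes of developing fibres rose. Ttk, a kinase of the mitotic checkpoint, changed by -3.28 ± 0.25 with adjusted p = 3.80e-07, Cdca3, a cell division gene, by -3.21 ± 0.24, Cx3cr1, the fractalkine receptor of monocytes, by -3.13 ± 0.24 and Ptx3, a pentraxin of innate immunity, by -3.10 ± 0.32. The largest rises were in Scd, a fatty acid desaturase (3.55 ± 0.40 with adjusted p = 1.22e-05), and Klk1, a kallikrein (3.41 ± 0.25). Atp1b4, of the sodium pump beta family (3.34 ± 0.28), and Gnas (3.33 ± 0.40), dim at day 3 (1.89 to 2.52), followed. Myh3 rose by 3.04 ± 0.35 with adjusted p = 1.41e-05.

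Of the cell cycle genes 0 of 25 rose and 25 fell (median -1.90, adjusted p = 1.72e-28), among them Rrm2 (-3.02 ± 0.35), the cyclin-dependent kinase Cdk1 (-2.84 ± 0.23) and the motor Kif11 (-2.48 ± 0.22). Of the macrophage genes 0 of 20 rose and 20 fell (median -1.36, adjusted p = 7.49e-23), with Msr1 (-2.58 ± 0.29), Itgam (-2.16 ± 0.23) and Cd68 (-1.61 ± 0.19). Of the cytokines and chemokines 0 of 23 rose and 11 fell (1 and 13 adjusted over the list alone, median -0.55, adjusted p = 3.41e-05), with Il1rn (-2.94 ± 0.33), Il18 (-2.43 ± 0.22) and Ccl2 (-1.55 ± 0.30). Cd8a (-2.85 ± 0.22) and Cd8b (-1.14 ± 0.26) fell, while of the lymphocyte list 1 of 17 rose and 2 fell (median 0.18, adjusted p = 0.569, with signs that differed). Of the red blood cell genes 0 of 4 rose and 2 fell (median -0.82, adjusted p = 0.0335, adjusted p = 0.339 with an estimated correlation). The red blood cell call was lost without the dimmest 25% of genes, day 3 replicate 3 (-0.46) or day 7 replicate 3 (-0.77).

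Of the developmental contractile and receptor genes 5 of 6 rose and 0 fell (median 1.65, adjusted p = 2.17e-05), with Tnnt2 (2.23 ± 0.33) and Chrna1 (1.87 ± 0.44). Of the calcium handling genes 8 of 11 rose and 0 fell (median 0.66, adjusted p = 1.44e-06), with Jph2 (1.15 ± 0.24), Sln (1.08 ± 0.25) and Jph1 (0.98 ± 0.16). Of the neuromuscular junction genes 6 of 11 rose and 2 fell (median 0.71, adjusted p = 0.00355, adjusted p = 0.117 with an estimated correlation), with Chrne, the adult subunit of the acetylcholine receptor (1.30 ± 0.15). Of the myogenic genes 7 of 18 rose and 4 fell (8 and 4 adjusted over the list alone, median 0.17, adjusted p = 0.0273, adjusted p = 0.154 with an estimated correlation), with Mymk (2.43 ± 0.31) and Megf10 of satellite cells (1.20 ± 0.15). This call was lost under both centrings, without the dimmest 50% of genes and without day 7 replicate 1 (median 0.07). Of the slow-fibre genes 6 of 11 rose and 2 fell (median 0.76, adjusted p = 0.0335, adjusted p = 0.41 with an estimated correlation), with Myh7 (1.02 ± 0.26 with adjusted p = 0.0121) and Casq2 (1.23 ± 0.24) higher and Ankrd2 lower (-1.54 ± 0.37). The slow-fibre call was lost under each other scaling, without the dimmest 25% or 50% of genes and without day 3 replicate 3 (0.61), day 7 replicate 1 (0.63) or day 28 replicate 2 (0.76). Of the fast-fibre genes 2 of 7 rose and 0 fell (median 0.32, adjusted p = 0.00774, adjusted p = 0.368 with an estimated correlation), with Casq1 (0.90 ± 0.14), a call lost under cyclic loess.

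Myod1 rose (0.76 ± 0.23 with adjusted p = 0.0297) and Myog fell (-0.91 ± 0.27 with adjusted p = 0.0291), and both calls were lost without single arrays. For Myod1 these were day 3 replicates 2 (0.68) and 3 (0.75) and day 7 replicate 4 (0.59). For Myog, whose call was also lost with only the compared groups fitted, they were day 3 replicates 2 (-0.93), 3 (-0.86) and 4 (-0.86) and day 7 replicate 3 (-0.58). Fbxo32 (-0.91 ± 0.20 with adjusted p = 0.00409) and Trim63 (-0.65 ± 0.14 with adjusted p = 0.00424) fell, whereas Myh4 (0.44 ± 0.21, adjusted p = 0.202) and Mstn (0.58 ± 0.31, adjusted p = 0.258) did not pass.

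Of the tricarboxylic acid cycle genes 3 of 14 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.32, adjusted p = 3.27e-04, adjusted p = 0.368 with an estimated correlation), with Idh3a (0.62 ± 0.13). Of the fatty acid oxidation genes 4 of 24 rose and 1 fell (median 0.22, adjusted p = 9.47e-04, adjusted p = 0.41 with an estimated correlation), with Ppargc1a (0.99 ± 0.19). Of the glycolysis and glycogen genes 5 of 12 rose and 0 fell (8 and 1 adjusted over the list alone, median 0.40, adjusted p = 3.28e-04, adjusted p = 0.339 with an estimated correlation), with Gys1 (0.98 ± 0.18). Of the oxidative phosphorylation genes 2 of 34 rose and 0 fell (1 and 0 adjusted over the list alone, median 0.14, adjusted p = 0.00774, adjusted p = 0.607 with an estimated correlation), with Atp5f1c (1.10 ± 0.19). That call was lost under cyclic loess and without day 3 replicate 4 (0.04) or day 7 replicate 3 (median 0.10). Of the ribosome biogenesis genes 0 of 23 rose and 11 fell (0 and 12 adjusted over the list alone, median -0.39, adjusted p = 2.17e-05, adjusted p = 0.118 with an estimated correlation), with Fbl (-0.72 ± 0.18). Of the unfolded protein response genes 0 of 17 rose and 9 fell (1 and 10 adjusted over the list alone, median -0.56, adjusted p = 2.87e-04, adjusted p = 0.142 with an estimated correlation), with Sdf2l1 (-1.64 ± 0.33). Of the pericyte and smooth muscle genes 3 of 9 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.48, adjusted p = 0.00174, adjusted p = 0.172 with an estimated correlation). Of the insulin-like growth factor system 3 of 11 rose and 0 fell (median 0.21, adjusted p = 0.0142, adjusted p = 0.0843 with an estimated correlation), with Irs1 (1.27 ± 0.22).

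Of the adipocyte genes 2 of 10 rose and 0 fell (median 0.43, adjusted p = 0.0389, adjusted p = 0.29 with an estimated correlation). The adipocyte call was lost under each other scaling, with an intensity trend, without the dimmest 25% or 50% of genes (0.16 for 50%) and without day 3 replicate 4 (0.41) or day 7 replicate 1 or 2 (0.44 each). Of the tenocyte genes 2 of 12 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.63, adjusted p = 0.0443, adjusted p = 0.404 with an estimated correlation). The tenocyte call was lost under each other scaling, with array weights, without the dimmest 25% or 50% of genes and without day 3 replicate 3 (0.58) or 4 (0.53) or day 7 replicate 1 (0.39) or 4 (0.54). Of the fibrillar collagens and matrix glycoproteins 4 of 21 rose and 1 fell (4 and 3 adjusted over the list alone, median 0.16, adjusted p = 0.266), a list that passed without day 3 replicate 4 (0.35). Col1a1 differed by 0.33 ± 0.22 (adjusted p = 0.386) and Col3a1 by -0.08 ± 0.15 (adjusted p = 0.819). Of the fibroblast markers 3 of 13 rose and 0 fell (4 and 1 adjusted over the list alone, median 0.27, adjusted p = 0.0928), a list that passed without day 3 replicate 2 (0.23) or 4 (0.25) or day 7 replicate 1 (0.30).

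In limma 2221 genes (15.3%) changed from day 3 to day 7, 877 higher and 1344 lower, and 635 at least 2-fold, 158 higher and 477 lower. Arrays did not overlap in 2616 genes (2.86% by chance). Of the lists, 14 were called upward and 6 downward. With an estimated correlation 2 upward calls (developmental and calcium handling genes) and 3 downward calls (macrophages, cell cycle and cytokines) held. The share that were higher was 39.5% as deposited, 56.9% after centring on all tested genes and 53.5% after centring on the brighter 50%.

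From day 7 to day 28 genes of developing fibres, of the matrix and of macrophages fell. Myh3 changed by -5.22 ± 0.35 with adjusted p = 1.49e-07, Tnnt2 by -4.04 ± 0.33, Cthrc1 by -4.03 ± 0.28 and Tnn, of the tenascin family, by -3.83 ± 0.51. The largest rises were those of Perm1 (2.40 ± 0.33 with adjusted p = 1.33e-04), Dynap (2.16 ± 0.51), Wnt16, a Wnt ligand (1.95 ± 0.32), and Slc16a3, a lactate transporter (1.91 ± 0.36).

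Of the developmental contractile and receptor genes 0 of 6 rose and 6 fell (median -2.19, adjusted p = 2.61e-09), with Chrna1 (-2.40 ± 0.44) and Chrng (-1.99 ± 0.20). Of the myogenic genes 1 of 18 rose and 9 fell (2 and 9 adjusted over the list alone, median -0.44, adjusted p = 0.00143), with Mymk (-3.18 ± 0.31) and Myog (-1.18 ± 0.27 with adjusted p = 0.00565). Of the neuromuscular junction genes 0 of 11 rose and 6 fell (median -0.54, adjusted p = 2.86e-04). Of the fibrillar collagens and matrix glycoproteins 1 of 21 rose and 18 fell (1 and 19 adjusted over the list alone, median -1.32, adjusted p = 6.99e-20), with Postn (-2.51 ± 0.20) and Col3a1 (-1.33 ± 0.15). Col1a1 fell from a mean of 11.78 to 9.78 with adjusted p = 1.88e-05. Of the proteoglycan and hyaluronan genes 0 of 15 rose and 6 fell (2 and 9 adjusted over the list alone, median -0.46, adjusted p = 5.03e-05), with Bgn (-2.20 ± 0.18). Of the matrix proteases 1 of 25 rose and 13 fell (1 and 14 adjusted over the list alone, median -0.73, adjusted p = 1.17e-08), with Lox (-2.12 ± 0.18) and Timp1 (-2.09 ± 0.32). Of the fibroblast markers 0 of 13 rose and 6 fell (0 and 7 adjusted over the list alone, median -0.31, adjusted p = 5.03e-05), with S100a4 (-2.42 ± 0.21) and Thy1 (-1.71 ± 0.31). Of the tenocyte genes 0 of 12 rose and 6 fell (median -0.61, adjusted p = 0.00108, adjusted p = 0.153 with an estimated correlation). Of the basement membrane genes 0 of 8 rose and 1 fell (median -0.23, adjusted p = 0.038, adjusted p = 0.193 with an estimated correlation). The basement membrane call was lost without the dimmest 25% or 50% of genes, under centring on all tested genes and without day 7 replicate 4 (median -0.21) or day 28 replicate 2 (-0.23) or 4 (-0.26).

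Of the macrophage genes 0 of 20 rose and 19 fell (0 and 20 adjusted over the list alone, median -1.26, adjusted p = 6.99e-21), with Gpnmb (-2.46 ± 0.18), Cd68 (-2.23 ± 0.19) and Ccr2 (-2.09 ± 0.24). Of the lymphocyte and natural killer genes 0 of 17 rose and 7 fell (0 and 10 adjusted over the list alone, median -0.83, adjusted p = 3.06e-05), with Cd8b (-1.54 ± 0.26) and Cd4 (-1.41 ± 0.21). Of the cytokines and chemokines 0 of 23 rose and 11 fell (median -0.63, adjusted p = 1.48e-07), with Ccl12 (-1.97 ± 0.19). Of the cell cycle genes 1 of 25 rose and 6 fell (median -0.37, adjusted p = 0.00243, adjusted p = 0.366 with an estimated correlation), a call lost without the dimmest 50% of genes. Of the heat shock and load-responsive sarcomere genes 1 of 14 rose and 7 fell (1 and 9 adjusted over the list alone, median -0.45, adjusted p = 8.70e-07, adjusted p = 0.0538 with an estimated correlation), with Ankrd1 (-3.15 ± 0.18 with adjusted p = 2.92e-08) and Ccn1 (-2.42 ± 0.24). Of the proteasome genes 0 of 24 rose and 3 fell (median -0.24, adjusted p = 6.09e-04, adjusted p = 0.452 with an estimated correlation). Of the insulin-like growth factor system 0 of 11 rose and 3 fell (median -0.12, adjusted p = 0.0428, adjusted p = 0.112 with an estimated correlation). The insulin-like growth factor call was lost without the dimmest 25% or 50% of genes, under cyclic loess, with the replicate block and without day 7 replicate 4 (-0.07) or day 28 replicate 2 (-0.07) or 3 (-0.21).

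Of the fatty acid oxidation genes 15 of 24 rose and 0 fell (22 and 0 adjusted over the list alone, median 0.60, adjusted p = 7.97e-11, adjusted p = 0.115 with an estimated correlation), with Acsl1 (1.02 ± 0.20) and Acadm (0.97 ± 0.16). Of the oxidative phosphorylation genes 16 of 34 rose and 0 fell (26 and 0 adjusted over the list alone, median 0.39, adjusted p = 1.30e-10, adjusted p = 0.153 with an estimated correlation), with Cyc1, cytochrome c1 (0.78 ± 0.14). Of the tricarboxylic acid cycle genes 12 of 14 rose and 0 fell (13 and 0 adjusted over the list alone, median 0.52, adjusted p = 8.72e-09, adjusted p = 0.129 with an estimated correlation), with Sucla2 (0.94 ± 0.14) and Idh3g (0.79 ± 0.12). Of the glycolysis and glycogen genes 6 of 12 rose and 0 fell (9 and 0 adjusted over the list alone, median 0.54, adjusted p = 3.88e-06, adjusted p = 0.153 with an estimated correlation), with Fbp2 (1.29 ± 0.33) and Phkg1 (1.24 ± 0.21). Of the endothelial genes 7 of 13 rose and 0 fell (8 and 0 adjusted over the list alone, median 0.60, adjusted p = 2.86e-04, adjusted p = 0.153 with an estimated correlation), with Cdh5 (1.22 ± 0.20) and Flt1 (1.07 ± 0.25). Sln fell (-3.50 ± 0.25). Fbxo32 rose by 0.82 ± 0.20 with adjusted p = 0.00762, and Myh4 (0.29 ± 0.21, adjusted p = 0.408), Mstn (0.23 ± 0.31, adjusted p = 0.695) and Trim63 (0.16 ± 0.14, adjusted p = 0.503) did not pass. Myh7 rose (0.80 ± 0.26 with adjusted p = 0.0425) and Myod1 fell (-0.69 ± 0.23 with adjusted p = 0.0426), and each call was lost with array weights, with only the compared groups fitted and without any of 9 arrays. The Myh7 call was also lost under cyclic loess and with the replicate block, and that of Myod1 under centring on all tested genes. For Myh7 these were day 0 replicate 2 or 3 and day 3 replicate 3 (0.80 each), day 7 replicate 2 (0.74), 3 (0.82) or 4 (0.64) and day 28 replicate 2 (0.85), 3 (0.73) or 4 (0.58). For Myod1 they were day 0 replicate 1 and day 3 replicate 1 or 3 (-0.69 each), day 7 replicate 1 (-0.71), 2 (-0.73) or 4 (-0.52) and day 28 replicate 2 (-0.67), 3 (-0.74) or 4 (-0.52).

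Over this interval 2566 genes (17.6%) changed in limma, 1200 higher and 1366 lower, and 597 at least 2-fold, 139 higher and 458 lower. Arrays did not overlap in 3071 genes (2.86% by chance). Lists were called upward in 5 cases and downward in 16, of which 0 and 10 held with an estimated correlation. The 10 were collagen, proteoglycan, matrix protease, developmental, myogenic, neuromuscular junction, macrophage, lymphocyte, cytokine and fibroblast genes. The share that were higher was 46.8% as deposited and 65.7% after centring on all tested genes.

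**Figure D4:**
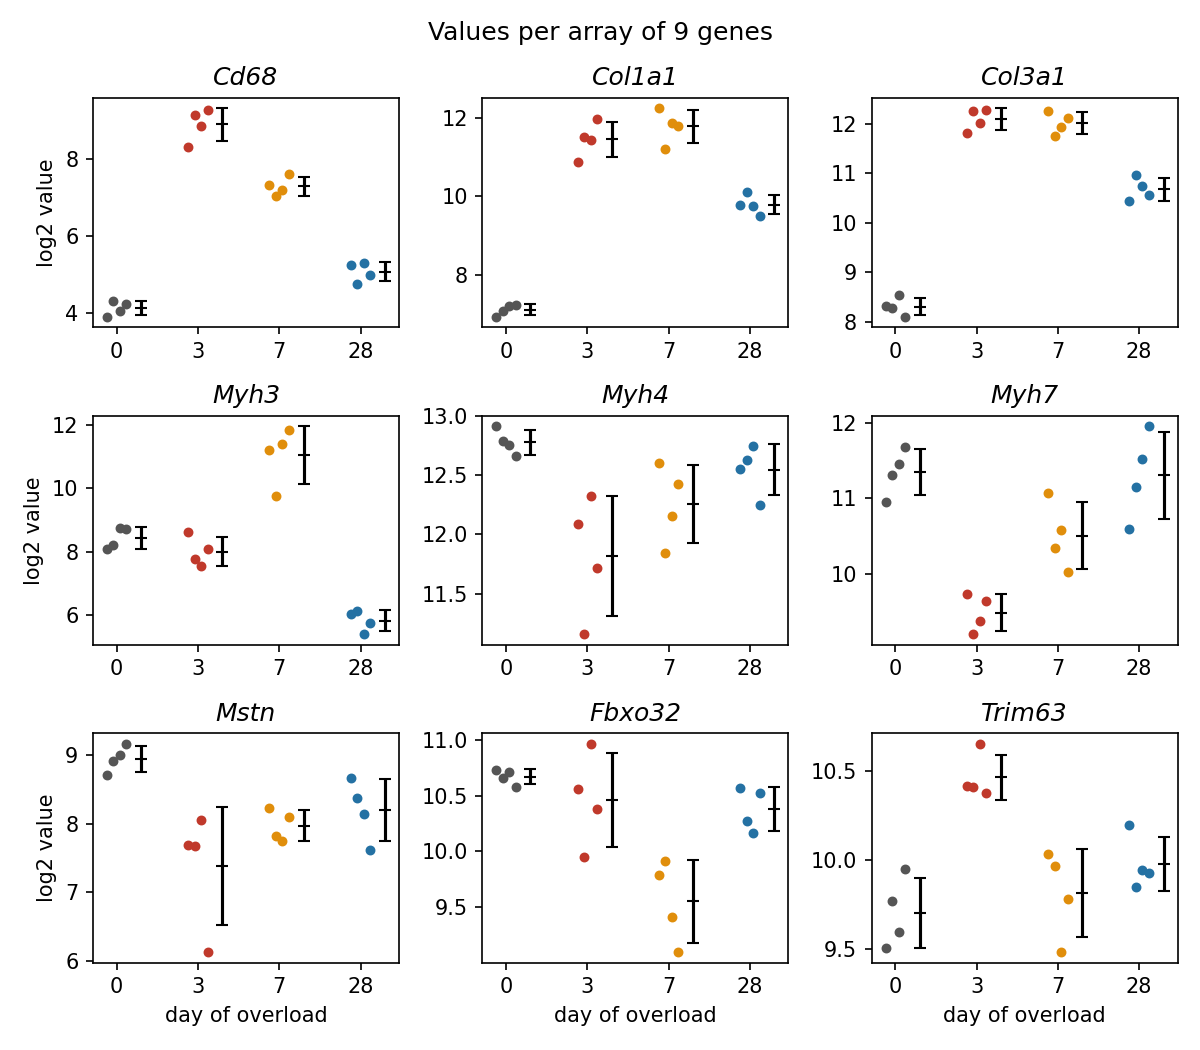
Log2 expression (vertical axis) of 9 genes on each array (dots, 4 per day) at days 0, 3, 7 and 28, with bars at the mean ± SD. Col1a1 has a mean of 7.11 at day 0 and 11.78 at day 7, Cd68 of 4.12 at day 0 and 8.90 at day 3, and Myh3 of 8.45 at day 0, 11.05 at day 7 and 5.83 at day 28.

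Across the time course the calls of the comparisons with day 0 overlapped. Of the 3156 genes that rose at day 3, 1212 fell from day 3 to day 7, 1091 fell from day 7 to day 28 and 775 were still above day 0 at day 28. Of the 2857 that fell, 575 rose from day 3 to day 7, 913 rose from day 7 to day 28 and 364 were still below at day 28. A peak at day 7, above each other day, was found for 148 genes, and a trough for 17. Of the 1323 genes called at day 28, 96 were called at neither day 3 nor day 7. Days 3 and 7 shared 3858 genes called in the same direction, days 3 and 28 shared 1139 and days 7 and 28 shared 1154, where independent lists would share 956.6, 278.4 and 214.9. These comparisons share the day 0 arrays, and in 100 draws of unchanged groups the highest number shared was 0, with a mean of 0.15 genes called. With the day 0 arrays split 2 and 2, the shared calls were 2669 to 2709, 472 to 659 and 461 to 648 over the 6 splits, against 609.6 to 627.0, 105.9 to 152.8 and 75.1 to 106.9 for independent lists. Across genes, log2 differences correlated at 0.86, 0.659 and 0.736, against 0.51 in unchanged groups, and their covariances of 0.5, 0.222 and 0.184 exceeded the 0.0239 of unchanged groups by 0.476, 0.198 and 0.16.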

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

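The tests of endothelial against macrophage genes, of the possible cell sources of Cd8a and Cd8b and of the other myosin clusters were chosen only after the results were seen, and the other tests of this part were set earlier.

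At day 3 the tricarboxylic acid cycle, fatty acid oxidation and glycolysis lists fell (adjusted p = 0.255, 0.287 and 0.219 with an estimated correlation) while macrophage genes rose. A lower share of fibre RNA, with the other cell types unchanged among themselves, would raise endothelial and macrophage markers alike, but the upper quartile of the endothelial list was -0.34 and the lower quartile of the macrophage list 3.58. Dilution by incoming cells would lower fibre genes of middle level alike only if those cells lack their RNA, which was untested. So 6 list medians spanning 1.91, from -1.44 for glycolysis (quartiles -1.94 to -1.12) to 0.47 for slow-fibre genes (-0.78 to 1.36), cannot decide. Oxidative phosphorylation had quartiles of -0.62 to 0.05. Scalings moved day 3 values by -0.46 to 0.10, too little to test scaling on the tricarboxylic acid cycle median (at most -0.72). Dilution stays open, as the tricarboxylic acid cycle (-0.91) and fatty acid oxidation (-0.84) medians were close. Lower transcription of these genes in loaded fibres remains an untested hypothesis.

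Cd8a and Cd8b rose at day 3 and fell by day 7. The 7 T cell genes had a median change of 0.47 to day 3 and 0.19 from day 3 to day 7. The 3 with a level above 4 (Cd3g, Lck and Cd5) had 0.18 to day 7, so this set did not fall. Natural killer cells cannot be told apart from other sources, because 0 of their 4 genes reached that level, with a median change of 0.41. The 11 early monocyte genes rose at day 3 (median 2.19) and changed by -0.81 to day 7, or -0.85 for the 9 above level 4. Monocytes that carry them are a candidate source. Chosen after the results, the list shares genes such as Ccr2, Ccl7 and Fn1 with other lists, so this is weak evidence. Other myeloid cells and T cells remain open.

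Myh3 was lower at day 28 than at day 0. Signal of related myosin genes on its probes is argued against by the other striated myosin heavy chain clusters with a mean above 5, whose lowest difference was -0.23, although the cluster shared by Myh1, Myh2 and Myh8 (-0.20) has a day 0 mean of 13.35 near the top of the scale and may be compressed. Scalings moved day 28 values by -0.25 to 0.01, too little to test scaling on Myh3 (at most -2.61). Loss of Myh3 transcripts already held by control muscle is a hypothesis the labels do not let be tested.

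Genes called at 2 days in opposite directions, with the direct difference also past the threshold in limma, numbered 19 for days 3 and 7, 12 for days 3 and 28 and 4 for days 7 and 28. The 4 were Ccn1, Clic4, Myh3 and Pvr, named after their values were seen. For days 3 and 7 they included Atp1b4, which differed by -1.67 and then 1.67. With arrays centred on all tested genes the numbers were 42, 46 and 15.

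A single array stood apart from the 3 others of its group in 5 of 176 groups tested, where chance gives about 8.8. Trim63 was 10.65 on day 3 replicate 3 and 10.37 to 10.41 on the others. The mean of the fast-fibre list was 12.4 on day 28 replicate 4 (others 12.58 to 12.62), and that of the developmental list 7.57 on day 3 replicate 4 (7.26 to 7.30). The lymphocyte list was at 3.76 on day 3 replicate 3 (3.96 to 3.98), and the TGF-beta list at 5.92 on day 3 replicate 2 (others 5.97).

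Clusters outside the tests of named genes also changed. Of the 829 with several symbols, 267, 193 and 25 changed at days 3, 7 and 28 against day 0, and of the 21032 with no listed symbol, 5406, 3611 and 489 did. Of the latter, 1809 were higher and 3597 lower at day 3.

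The 8 arrays of each comparison were split into 4 and 4 in 35 ways. Only the labelled one called as many genes as reported, the lowest share 35 splits allow. Mixed splits count day differences as spread and so call few genes. The test cannot exclude chance, or differences between animals if arrays share one. The labelled splits called 6013, 4617, 1323, 2221 and 2566 genes and the highest of the others 1, 0, 1, 1 and 1. At least 2-fold, they called 2472, 1432 and 365 against day 0, and the highest others 1, 0 and 1.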

How the results depend on the processing

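Centring on the brighter 50% of genes was chosen after the array medians had been seen, and the other alternatives earlier. No named gene or list test reversed direction where it was called in either setting, although the medians of some lists changed sign under a scaling. Of genes not called, centring on all tested genes turned Trim63 at day 7 (-0.25) and Myog at day 28 (-0.07) against day 0, and Col3a1 from day 3 to 7 (0.02). Col3a1 also turned with the brighter 50% (0.003) and without day 7 replicate 2 (0.01), and Myh7 at day 28 without day 0 replicate 4 (0.06) or day 28 replicate 1 (0.19) or 2 (0.006). The majority direction of changed genes did turn. Centring on all tested genes took the share that were higher from 52.5% to 18.2% at day 3, 53.2% to 16.8% at day 7 and 69.2% to 15.2% at day 28 against day 0, from 39.5% to 56.9% from day 3 to 7 and from 46.8% to 65.7% from day 7 to 28. Centring on the brighter 50% gave 37.7%, 44%, 53.7%, 53.5% and 48.4%. Over 11 settings that keep all arrays, up to 585 results for named genes were recomputed. The setting that moved most calls was the fit of only the compared groups, with 541 on the same side of the threshold, 43 no longer past it and 1 newly past it, followed by centring on all tested genes (545, 35 and 5). Cyclic loess gave 572, 13 and 0 and array weights 579, 6 and 0. Of 92 list calls, 35 held with the estimated correlation and 57 were lost. Of 165 list results, called or not, centring on all tested genes gave 151, 11 and 3, leaving out the dimmest 25% gave 155, 10 and 0, and leaving out the dimmest 50% gave 134, 16 and 0 of 150. Counts of changed genes moved over 1.5 times in 2 settings. With arrays centred on all tested genes 10321, 8442 and 3587 genes changed at days 3, 7 and 28 against day 0, and 7537, 3236 and 3174 were shared in direction by days 3 and 7, 3 and 28, and 7 and 28. Over all transcript clusters, where more are tested, 11693 and 8312 changed at days 3 and 7, 5613, 3252 and 625 at least 2-fold at days 3, 7 and 28, and 6833 were shared by days 3 and 7. Why array medians differed was not tested.

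Without 1 array at a time, the changed genes numbered 5486 to 6067 at day 3, 4019 to 4649 at day 7 and 904 to 1513 at day 28 against day 0, 1702 to 2290 from day 3 to 7 and 2037 to 2638 from day 7 to 28. At least 2-fold, they were 2347 to 2623, 1344 to 1537 and 336 to 397. Shared directions were 3402 to 3886 for days 3 and 7, 788 to 1277 for days 3 and 28 and 801 to 1294 for days 7 and 28. Of 9360 named gene results without 1 array, 8985 kept their side, 372 lost and 3 gained the threshold, and of 2640 list results 2591, 36 and 13 did.

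The labels do not say that a replicate number marks a shared animal or batch, and the correlations did not reach 0.1. The 24 same-numbered pairs of arrays had correlations of -0.036 to 0.092 (median 0.019) between their deviations from group means, against a median of -0.007 in 72 other pairs, and 9 of 16 arrays matched their own number best. Over 13824 relabellings of the numbers, a test chosen afterwards, the mean was 4 and 2.7% gave at least 9, a hint of pairing from the data and not the design. With the replicate number as a block, 6050, 4586, 1344, 2204 and 2564 genes changed in the 5 comparisons as ordered in the report, and as a random block the correlation was 0.0074. The fixed block ended 11 calls of named genes and 2 of lists. The number of arrays and the compression of dim and very bright clusters limit these values.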

Other observations

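The 12 gene lists of this part, the test of imprinted genes and the genes named here were chosen only after the main results had been seen. At day 3 against day 0, 14 of 14 measured antigen presentation genes rose (median 1.54, adjusted p = 4.95e-08 over the 12 lists), 15 of 19 lysosome genes (0.93, 5.07e-08) and 4 of 6 complement genes (1.73, 4.38e-04), and 0 fell. Of the oxidative stress response genes 10 of 16 rose and 2 fell (0.97, 4.69e-04). Genes of fibre channels and the sodium pump, with no chloride channel measured, fell in 7 of 10 cases (-1.55, 6.74e-05). Circadian clock genes fell in 7 of 11 (-0.59, 0.00232), but the labels give no time of day. These 6 calls and that of the 11 early monocyte genes (8 rose, 1 fell, median 2.19, 4.31e-05) held with an estimated correlation. At day 28 complement genes were higher (4 of 6, 0.87, adjusted p = 0.047 with an estimated correlation). Fibre channel and pump genes were lower (3 of 10, -0.25, 0.047), but their day 7 call was lost (adjusted p = 0.0888 with an estimated correlation).

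The other calls at day 3 were lost with an estimated correlation. They were those of cytosolic ribosomal proteins (20 of 24 rose, median 0.82, adjusted p = 2.15e-07, and adjusted p = 0.112 with an estimated correlation), interferon-stimulated genes (5 of 15, 0.49, 0.0323, and 0.339), cholesterol synthesis (9 of 14 rose and 1 fell, 0.62, 0.00477, and 0.114), and amino acid transport (8 of 16 rose and 3 fell, 0.53, 0.024, and 0.109). Imprinted genes gave 2 of 21 higher and 8 lower (-0.42, 0.0443, and 0.0949). From day 3 to day 7 cholesterol synthesis genes fell in 10 of 14 (-0.80, 9.13e-08, and 0.018). Lists of fibre channels and pumps (5 of 10 higher, 0.52, and 0.0143) and oxidative stress (9 of 16 lower and 2 higher, -0.73, and 0.0326) also held.

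Several of the genes with a peak at day 7 are imprinted, among them Cdkn1c, Dlk1, Gnas, Grb10 and H19. The imprinted list was chosen for these 5, so its change to day 7 was tested on the 16 others. From day 3 to day 7, 4 of them rose and 0 fell (median 0.27, p = 0.00394, and p = 0.0204 with an estimated correlation), after 2 rose and 7 fell at day 3 against day 0 (-0.48, p = 0.0466, and p = 0.0902). At day 7 against day 0 their median was -0.08, with 3 higher and 4 lower (p = 0.662, and p = 0.692 with an estimated correlation). The hypothesis that imprinted genes may move as a group at day 7 stays open, since leaving out genes found by their day 7 peak lowers the median of the rest.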
